A study of Mus musculus with 17 samples.

How the data were processed

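RNA was measured on 17 Affymetrix Mouse Gene 1.0 ST arrays, each hybridized with biotin-labelled cDNA made from about 100 ng of total RNA, per the labels' protocols. The cells were 3134 mouse mammary epithelial cells carrying a tetracycline-regulated transactivator. Per the labels' protocols, stocks were kept in 5 µg/ml tetracycline, which represses the transactivator, and were then plated with or without tetracycline for 48 h. Removal of the drug induced the transactivator alone in the control line, or the transactivator together with a Flag-tagged dominant-negative form of Brg1, Chd4 or Snf2h in the other lines. Groups were taken from the sample titles: the control line had 2 repressed and 3 induced arrays, and each dominant-negative line had 2 repressed and 2 induced arrays. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

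The deposited table held 1 value per probe set and array on a log2 scale, as judged from its values, which ran from 2.02 to 14.86 with array medians between 5.48 and 5.63 and no missing value. Per the submitters' processing notes the arrays were processed with Affymetrix Expression Console. Its version, the summarization and normalization method and the genome build are not given in the sources used here, and no coordinates were used. The deposited log2 values were analysed without further scaling. An array gives no read depth, and no background values were used here.

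Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 had none. The reference gene table held 21698 of the singly named probe sets by gene number, and no symbol needed updating. For the 999 genes with more than 1 singly named probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes for testing. Genes were named only from probe sets with 1 symbol.

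All 8 groups were fitted together with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes). P-values were adjusted by the Benjamini-Hochberg method over genes, with 0.05 as the threshold, and every adjusted p of a gene given here comes from limma. The 13 contrasts were the induction in each of 4 lines (induced minus repressed), each dominant-negative induction minus the control induction, the 3 differences between dominant-negative inductions, and each repressed dominant-negative line minus the repressed control line. The last 3 share the control arrays, and no overlap between them was counted. Overlaps of calls between inductions were set beside the number that independent lists would give (n1 × n2 / N per direction). Correlations of fold changes ran across genes, which are not independent replicates, so they carry no p.

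Gene lists were tested with camera (two-sided, preset inter-gene correlation 0.01), adjusted over the lists of a contrast. The 25 lists held 491 entries, of which 467 were measured, with Sesn2 counted in both the p53 and the ATF4 list. They were SWI/SNF, NuRD and ISWI complex subunits; extracellular matrix and adhesion; matrix proteases; epithelial, myoepithelial and basal, mesenchymal and fibroblast, macrophage and adipocyte markers; milk and luminal secretory genes; S phase and DNA replication; G2 and mitosis; p53 targets; interferon response; NF-kB and cytokine genes; glucocorticoid receptor targets; immediate early and AP-1 genes; cholesterol synthesis; unfolded protein response; ATF4 and amino acid stress; nuclear genes of oxidative phosphorylation; glycolysis and hypoxia; germline genes; and imprinted genes. A list of 39 lysosome genes, 35 of them measured, was added after the data were seen.

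Genes were named by rule. For an induction these were the 10 highest and 10 lowest fold changes past the threshold with all induced arrays on one side of all repressed arrays, filled to 5 by smallest p where fewer passed. For a difference the rule took the 4 highest and 4 lowest, filled to 2, and for a repressed line the 3 highest and 3 lowest. For the overlap it took up to 8 per direction that passed in every dominant-negative line and not in the control line. For a list and a line it took the 3 members with the smallest adjusted p, or the member with the largest change where none passed. Smarca4, Chd4, Smarca5, Smarca2, Smarca1, Chd3 and Nr3c1 were always included. Predicted and clone names and olfactory, vomeronasal, microRNA and small nucleolar RNA genes were passed over.

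The groups, contrasts, tests, lists, naming rule and other settings to be tried were fixed before the data were examined. Those settings were a fit of only the groups of a contrast, the replicate number as a block, trended and robust eBayes, array weights, removal of the dimmest 30% of genes (mean log2 value under 4.77), quantile normalization, median centring, all probe sets, each array left out in turn, an estimated inter-gene correlation and fry for the lists, and a direct comparison of induced lines. After the data were seen, a fit of 15 arrays was added that leaves out the libraries labelled control repressed replicate 1 and control induced replicate 1, because each grouped with the other label. Labels were never changed. In that fit the control line has 1 repressed and 2 induced arrays, and the lone array is assumed to vary like the other groups. The naming rule, written for 17 arrays, was also applied to the 15-array fit. The fit of 1 line alone uses only its own arrays, 4 for a dominant-negative line. Residual degrees of freedom were 9 with 17 arrays and 7 with 15, and the median residual SD over genes was 0.14 and 0.109 log2 units.

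The fit was tested on simulated data for the dnBrg1 induction, over 19938 genes of which 200 were changed. With 17 arrays it recovered 43.3% of the 67 genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, and called 5 unchanged genes. With 15 arrays the shares were 86.6%, 100% and 100%, with 13 unchanged genes called. The simulation drew equal noise for every array of a gene and changed genes picked at random. In the real data the disagreeing control arrays widen the 17-array spread of some changed genes. Slc7a11 in dnBrg1, for instance, had SE 0.824 with 17 arrays and 0.151 with 15. The 17-array shares therefore do not apply to such genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.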

Results

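Genome-wide RNA levels were measured on 17 arrays from 3134 cells, a mouse mammary epithelial line, in 4 stable derivatives. The control derivative carried the tetracycline-regulated transactivator alone. The others added a dominant-negative form of an ATP-dependent chromatin remodeler: Brg1 (gene Smarca4, the motor of SWI/SNF complexes), Chd4 (a motor of NuRD) or Snf2h (gene Smarca5, the motor of ISWI complexes). RNA was taken 48 h after cells were plated with tetracycline (repressed) or without it (induced). There were 2 control repressed, 3 control induced, and 2 repressed and 2 induced arrays for each of dnBrg1, dnChd4 and dnSnf2h. The series asked how far the remodelers act on the same genes, which the induction in each line, the differences between inductions and the overlap of their calls address. Values are log2 signals, and fold changes are differences of group means. The median fold change of every contrast lay between -0.0347 and 0.00804, and another scaling of the arrays moved no median by more than 0.0755.

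The targeted genes were examined first. The Chd4 probe set read 10.56 and 10.35 in the repressed dnChd4 arrays and 12.27 and 12.27 in the induced ones. Chd4 rose by 1.82 (SE 0.124, 3.53-fold; limma adjusted p = 1.56e-05) and was near 10 in the other lines. Smarca4 did not move measurably in the dnBrg1 line, with 9.56 ± 0.14 (SD, n = 2) repressed and 9.67 ± 0.08 (SD, n = 2) induced, a change of 0.12 (SE 0.119; adjusted p = 0.772). Smarca5 read 9.75 ± 0.09 (SD, n = 2) and 9.51 ± 0.11 (SD, n = 2) in the dnSnf2h line, a change of -0.24 (SE 0.141; adjusted p = 0.482). The species and part of each cDNA are not given in the sources used here, so a probe set need not see the transgene, and only the dnChd4 labels are checked by these values. Among related motors, Smarca2, the alternative SWI/SNF motor, changed by -0.68 in dnBrg1 (SE 0.147; adjusted p = 0.0785), which passed with that line alone (adjusted p = 0.00626) and with 15 arrays (adjusted p = 0.00149). For Smarca2 the repressed dnBrg1 arrays read 9.52 and 9.24 and the induced ones 8.69 and 8.73. Repressed arrays of the other lines read between 8.07 and 8.88, so the fall began from a higher level. Chd3, the NuRD motor related to Chd4, passed in no line with 17 arrays. With 15 arrays it rose in all 4, by 0.43 in control (adjusted p = 0.0141), 0.53 in dnBrg1, 0.56 in dnChd4 and 0.38 in dnSnf2h (adjusted p = 0.0113), where the control estimate with 17 arrays was -0.02. Smarca1 changed by between -0.19 and -0.02 and the glucocorticoid receptor gene Nr3c1 by between -0.02 and 0.15, with no call.

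The control arrays did not group by their labels. The library labelled control repressed replicate 1 correlated best with control induced replicate 2 (r = 0.995 across genes), and the libraries labelled control repressed replicate 2 and control induced replicate 1 correlated best with each other (r = 0.994). Adgrg1, an adhesion receptor gene, read 8.81 ± 2.41 (SD, n = 2) in the arrays labelled control repressed and 9.40 ± 1.89 (SD, n = 3) in those labelled control induced. In the 3 dominant-negative lines its SD was between 0.00 and 0.14. Slc7a11, the cystine transporter gene, read 6.87 ± 1.93 (SD, n = 2) and 6.59 ± 1.52 (SD, n = 3) in the control groups. Across genes, control repressed replicate 1 minus replicate 2 followed the mean induction of the dominant-negative lines with r = 0.798, and control induced replicate 1 minus replicate 2 with r = -0.815. Replicate pairs of the other lines gave values between -0.0982 and 0.149. Every contrast that uses these arrays, and every gene's pooled spread in the 17-array fit, carries this disagreement. Results are therefore given with 17 arrays, for each line alone, and with 15 arrays after both doubted libraries were left out, a fit chosen after the data were seen. The direction of the control induction with 15 arrays follows from that choice: the 2 arrays left out, induced minus repressed by label, gave r = -0.815 with the same mean.

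**Figure D1:**
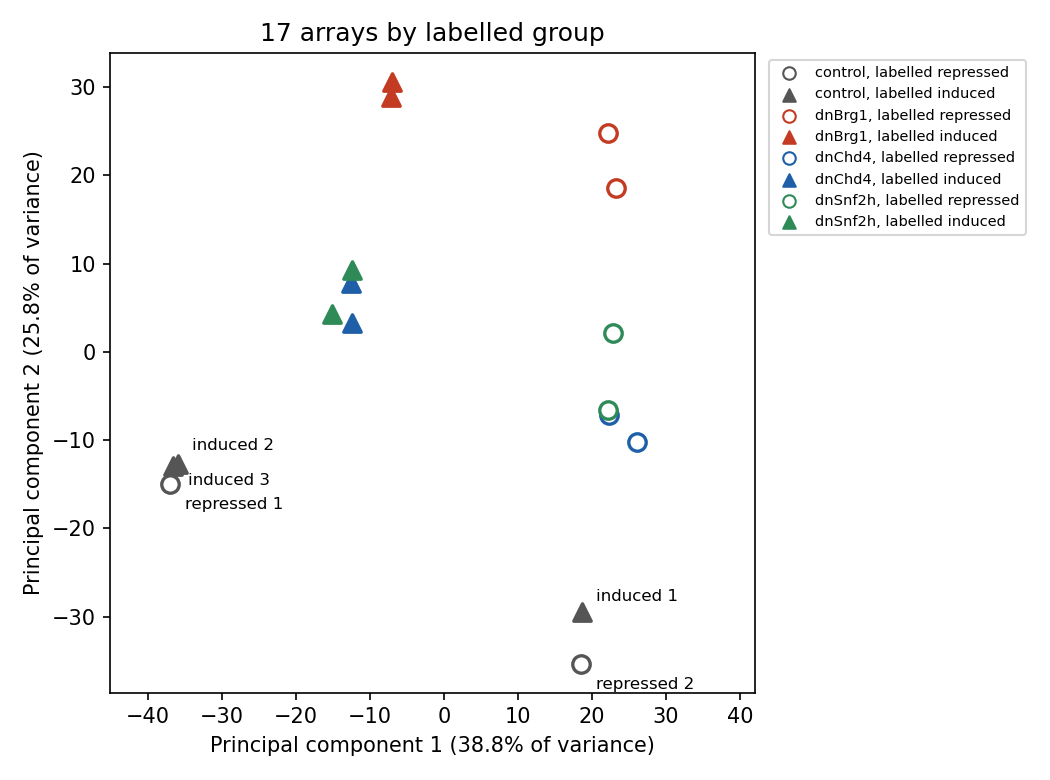
First 2 principal components of the log2 signals of the 17 arrays (axes in component units, with 38.8% and 25.8% of the variance), marked by labelled line and state; open circles are labelled repressed and triangles induced. The control arrays labelled repressed replicate 1 and induced replicate 1 each sit with the arrays of the other control label, while the 12 arrays of the other lines separate along the first component by label.

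In the control line, where only the transactivator was induced, no gene passed with 17 arrays. The count at an unadjusted limma p under 0.05 was 845, and the 5 control arrays alone gave 0 calls and 237 at an unadjusted p under 0.05. The smallest p-values with 17 arrays belonged to genes that did not pass, such as Traf5 at 0.47, Cyp3a13 at 0.48, Oaz3 at 0.33, Meis1 at 0.40 and Csad at 0.35 on the higher side, and Reg2 at -0.47, Dio3 at -0.63, Il23a at -0.46, Oas3 at -0.46 and Abhd16b at -0.52 on the lower side (adjusted p between 0.941 and 0.994). With 15 arrays 3070 genes rose and 2240 fell, 2949 of them at least 1.5-fold. Adgrg1 then rose by 3.38 (SE 0.120, 10.4-fold; adjusted p = 9.47e-11), with the glutathione transferase gene Gstm5 at 3.15, Tcp11l2 at 3.13, the retinaldehyde dehydrogenase gene Aldh1a1 at 2.93, Cpeb4 at 2.89, the adhesion molecule gene Mcam at 2.87, Fkbpl at 2.66, Lcp1 at 2.61, Naip5 at 2.60 and Gdf11 at 2.54. The neutrophil chemokine gene Cxcl3 fell by 2.60 (SE 0.178; adjusted p = 7.76e-08), Slc7a11 by 2.52, the glycine transporter gene Slc6a9 by 2.51, the mitochondrial folate enzyme gene Aldh1l2 by 2.44, Cxcl5 by 2.41, the glutamine transporter gene Slc1a5 by 2.26, Snhg5 by 2.11, Slc6a15 by 2.11, Trib3 by 2.09 and Dynap by 2.06. These calls compare 1 repressed with 2 induced arrays. With 17 arrays the same contrast gave Adgrg1 0.59 (SE 0.924) and Slc7a11 -0.27 (SE 0.753).

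Induction of dnBrg1 changed genes in both directions. Csnk1g1, a casein kinase 1 gene, rose by 3.01 (SE 0.18, 8.05-fold; limma adjusted p = 4.87e-06), from 7.16 ± 0.20 to 10.17 ± 0.05 (SD, n = 2 each), and Auts2, which encodes a Polycomb-associated protein, rose by 2.16 (SE 0.115; adjusted p = 2.25e-06). The iron exporter gene Slc40a1 rose by 1.72 (SE 0.117; adjusted p = 1.14e-05), the heme oxygenase gene Hmox1 by 1.36 (adjusted p = 0.0368) and the fatty acid receptor gene Cd36 by 1.41 (adjusted p = 4.06e-05). Rnd1 (1.71), Mfsd13a (1.56), Serpini1 (1.46), the heparan sulfate sulfotransferase gene Hs3st1 (1.45) and Loxl4 (1.31) also rose. The repressed levels of Slc40a1, Cd36 and Serpini1 lay under 4.77, a dim level, so their rises are lower bounds if such readings are background. The monocyte chemokine gene Ccl7 fell by 2.62 (SE 0.171; adjusted p = 9.16e-06). Among single genes, Saa3 fell by 2.03 (adjusted p = 0.000397), Lcn2 by 1.53, Orm3 by 1.28 and Ptx3 by 1.23. So did the water channel gene Aqp1 (-2.06), Cxcl12 (-1.91), Eno3 (-1.55), the lysyl oxidase gene Loxl1 (-1.41) and the stromelysin gene Mmp3 (-1.28). In all 36 genes rose and 32 fell. The line alone gave 1622 and 1316, and 15 arrays gave 1673 and 1303, of which 974 changed at least 1.5-fold. The latter fits shared 2699 calls with none in opposite directions, and 15 arrays kept all 68. Leaving out 1 array moved the count between 20 (without dnBrg1 induced replicate 2) and 426 (without the library labelled control induced replicate 1). With 15 arrays the rule also named Dhx40 (2.12), Tcp11l2 (1.91), Cyp2b13 (1.72, from a dim level of 3.44), H2bc4 (1.62) and the sialidase gene Neu1 (1.53) on the higher side, and Aldh1l2 (-2.29), Cxcl5 (-2.25), the ceruloplasmin gene Cp (-2.01), Slc7a11 (-1.85), S100a4 (-1.68) and the matrix proteoglycan gene Vcan (-1.65) on the lower side.

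In the dnBrg1 line, 16 mesenchymal and fibroblast markers were lower as a list (camera adjusted p = 0.000893). That call was lost with an estimated correlation (adjusted p = 0.52). With 15 arrays 6 of them fell and 0 rose (7 and 0 adjusted over the list alone), led by S100a4, the transcription factor gene Snai2 (-1.43) and Zeb2 (-0.74, which alone also passed with 17 arrays). S100a4 was also lower in control, by 1.51 with 15 arrays, so its fall is not shown to be special to dnBrg1. Snai2 also changed by -1.19 in dnChd4 and -1.30 in dnSnf2h, so its fall was not special to dnBrg1. Of 24 NF-kB and cytokine genes, 7 fell and 2 rose with 15 arrays (7 and 2 adjusted over the list alone), with Ccl7, Cxcl5 and Ccl2 (-0.82) leading. Only Ccl7 passed with 17 arrays (6 fell and 1 rose adjusted over the list alone). This list was lower (camera adjusted p = 0.0263; adjusted p = 0.494 with an estimated correlation). Cxcl5 also changed by -1.11 in dnChd4 and -1.41 in dnSnf2h, so its fall was not special to dnBrg1. In control it changed by -2.41 with 15 arrays and -0.71 with 17. The 21 p53 targets were higher (camera adjusted p = 0.00308; adjusted p = 0.494 with an estimated correlation), and 7 rose with 15 arrays (9 adjusted over the list alone), among them the death receptor gene Tnfrsf10b (0.92), Btg2 (0.45) and Rrm2b (0.50). Nuclear genes of oxidative phosphorylation were slightly higher, with a median of 0.10 over 27 genes (camera adjusted p = 0.0132; adjusted p = 0.745 with an estimated correlation), and 2 of them, Ndufa1 (0.45) and Ndufa9 (0.33), rose with 15 arrays (2 adjusted over the list alone). The 20 glucocorticoid receptor targets went both ways. With 15 arrays 6 rose and 6 fell (6 and 6 adjusted over the list alone), with the transglutaminase gene Tgm2 at 1.00 and the kinase gene Sgk1 at -0.85 (camera adjusted p = 0.891).

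Induction of dnChd4 mainly raised genes. Susd2, a membrane protein gene, rose by 2.92 (SE 0.166, 7.58-fold; limma adjusted p = 2.52e-06), from 4.63 ± 0.14 to 7.55 ± 0.25 (SD, n = 2 each). Its repressed level, like those of Cd74, Pld4, Muc13, Ly6f, Lcp1 and Ms4a4d below, lay under the mean of 4.77 that bounds the dimmest 30% of genes, so these rises are lower bounds if such readings are background. Cd74, the invariant chain gene of class II antigen presentation, rose by 1.5 (SE 0.0823; adjusted p = 2.52e-06), the endolysosomal exonuclease gene Pld4 by 2.16 (adjusted p = 0.000183), the addressin gene Madcam1 by 1.93 (adjusted p = 4.2e-05) and Ly6f by 1.40. The smooth muscle gene Tagln rose by 2.53 (SE 0.372; adjusted p = 0.0195), the mucin gene Muc13 by 1.86, the growth factor gene Igf1 by 1.61 and the junction gene Cgnl1 by 1.33 (adjusted p = 0.0264). Zfp36l1, which encodes an mRNA decay factor, was the 1 gene that fell, by 0.88 (SE 0.0981; adjusted p = 0.00163). The next lower genes did not pass: Usp43 at -0.68, Cdsn at -0.97, Rhebl1 at -0.49 and Dtwd1 at -0.92 (adjusted p between 0.12 and 0.218). In all 18 genes rose and 1 fell. The line alone gave 2521 and 1647, and 15 arrays gave 2322 and 1425, of which 1356 changed at least 1.5-fold. These latter fits shared 3522 calls, and 15 arrays kept all 19, again with the same fold changes in every fit. Leaving out 1 array moved the count between 8 (without dnChd4 induced replicate 1) and 262 (without the library labelled control induced replicate 1). With 15 arrays the largest rises were Mcam at 3.78 (13.7-fold), Aldh1a1 at 3.39, Adgrg1 at 3.34, Gstm5 at 3.21, Lcp1 at 2.91, the smooth muscle actin gene Acta2 at 2.56, Ms4a4d at 2.41 and Tcp11l2 at 2.35. The largest falls were in Slc7a11 (-2.58), Cxcl3 (-1.93), Aldh1l2 (-1.91), Trib3 (-1.73), Slc1a5 (-1.61), Slc6a9 (-1.46) and Slc6a15 (-1.32), with Snhg5 (-1.42), Cdca7 (-1.35) and the connexin gene Gja1 (-1.34).

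In dnChd4, p53 targets were higher (camera adjusted p = 0.000148; adjusted p = 0.209 with an estimated correlation), and 10 of 21 rose and 0 fell with 15 arrays (10 and 1 adjusted over the list alone), including Perp (0.88), Tnfrsf10b (1.11) and Sesn1 (0.72). The 17 matrix proteases were higher (camera adjusted p = 0.0397; adjusted p = 0.209 with an estimated correlation and 0.0734 with 15 arrays), with 4 risen and 0 fallen with 15 arrays (4 and 0 adjusted over the list alone), among them Mmp19 (1.38), the urokinase gene Plau (1.00) and Adamts4 (0.40). Of 14 macrophage markers, Cd74 and Cd68 (1.03) rose with 17 arrays (3 adjusted over the list alone), and the lysozyme gene Lyz2 (1.74) with 15 (3 adjusted over the list alone). The remaining 11 did not pass, and the list had no call (camera adjusted p = 0.138). Of the 12 myoepithelial and basal markers Tagln alone passed with 17 arrays (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.234). With 15 arrays 3 rose, Acta2 among them, and 1, the basal keratin gene Krt14, fell by 1.15 (3 and 1 adjusted over the list alone). Of 14 NuRD subunits Chd4 itself alone rose with 17 arrays (1 adjusted over the list alone; camera adjusted p = 0.118). With 15 arrays 5 rose, Chd3 and Hdac1 (0.52) among them, and 1 fell (6 and 1 adjusted over the list alone).

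Induction of dnSnf2h gave 1 call with 17 arrays. Zfp36l1 fell by 0.90 (SE 0.0981; adjusted p = 0.0108), from 7.87 ± 0.00 to 6.96 ± 0.01 (SD, n = 2 each), and limma gave 2443 genes at an unadjusted p under 0.05. This call was lost when each array was centred on its median (0 calls). The genes nearest to passing were Cgnl1 at 1.47 (SE 0.205; adjusted p = 0.0502), the interferon-induced GTPase gene Gbp3 at 0.63, Pla2g2e at 0.94, Ninj1 at 0.58 and Hyal3 at 1.07. On the lower side they were Sorbs2 at -0.98 (adjusted p = 0.0502), Uhrf2 at -0.98, the nitric oxide synthase gene Nos2 at -0.82 and Saa3 at -1.29 (adjusted p = 0.0644). The line alone called 766 rises and 680 falls, and 15 arrays called 1930 and 1729, of which 1284 changed at least 1.5-fold. These shared 1445 calls, again with the same fold changes in both fits. The 17-array count ran from 0 (without dnSnf2h repressed replicate 2 or dnSnf2h induced replicate 1) to 128 (without the library labelled control induced replicate 1) when 1 array was left out. With 15 arrays Adgrg1 rose by 2.75 (SE 0.098; adjusted p = 1.01e-10), Aldh1a1 by 2.65, Acta2 by 2.32, Tcp11l2 by 2.26, the natriuretic peptide gene Nppb by 2.06, Mcam by 2.02, Rptor by 1.98, Gstm5 by 1.95, Fkbpl by 1.75 and Grk4, from a dim level of 4.33, by 1.73. Slc7a11 fell by 2.75 (SE 0.151; adjusted p = 1.33e-08), Aldh1l2 by 2.33, Slc6a9 by 2.02, Cxcl3 by 2.01, Trib3 by 1.87, Slc1a5 by 1.78, Snhg5 by 1.62, Cp by 1.54, Gja1 by 1.53 and Mthfd1l by 1.53. Interferon response genes were higher in this line (camera adjusted p = 2.98e-05; adjusted p = 0.155 with an estimated correlation). Of 22 measured, 8 rose and 0 fell with 15 arrays (9 and 0 adjusted over the list alone), led by Irf9 (0.76), Irf7 (0.82) and Gbp3. Irf7 was also higher in control, by 1.13 with 15 arrays and 0.31 with 17, so its rise is not shown to be special to dnSnf2h.

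**Figure D2:**
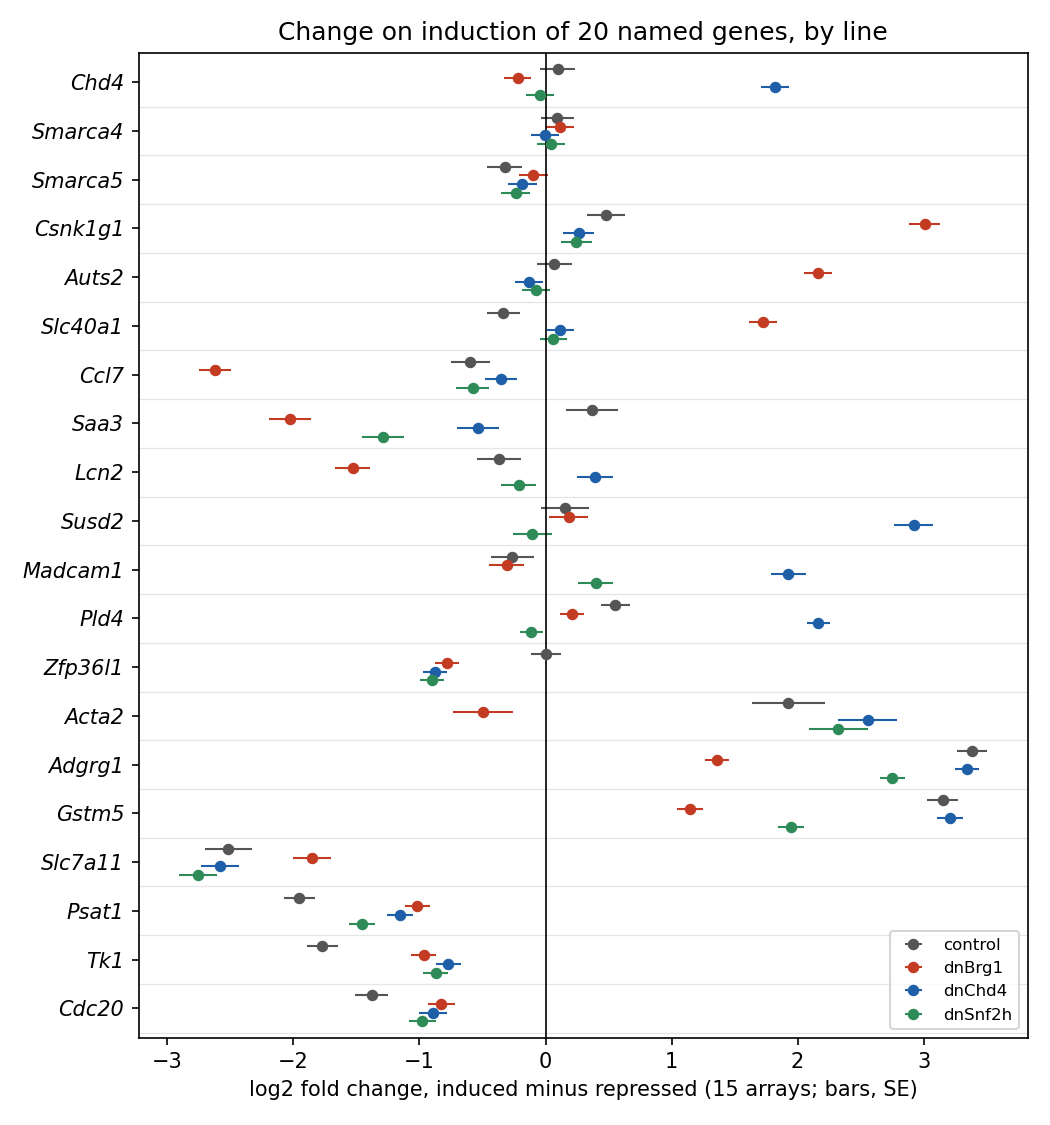
Log2 fold change on induction (induced minus repressed, 15 arrays) of 20 named genes in the control, dnBrg1, dnChd4 and dnSnf2h lines; points are estimates and bars standard errors. Chd4 and Susd2 stand at 1.82 and 2.92 in dnChd4 and near 0 elsewhere, Csnk1g1 at 3.01 in dnBrg1, and Zfp36l1 lies between -0.90 and -0.78 in the 3 dominant-negative lines and at 0.00 in control.

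The G2 and S phase lists had mostly lower members in every line with 15 arrays, where the control direction rests on which arrays were left out. All 25 G2 and mitosis genes fell in control and dnSnf2h and 24 of 25 in dnBrg1 and dnChd4 with 15 arrays (25 in each line adjusted over the list alone). Their median was -1.38 in control, -0.76 in dnBrg1, -0.74 in dnChd4 and -0.78 in dnSnf2h. The spindle checkpoint gene Cdc20 changed by -1.38, -0.83, -0.89 and -0.98 in that order, and the kinase gene Aurkb by -1.44, -0.89, -0.83 and -0.91. With 17 arrays no single member passed. Camera gave adjusted p = 7.63e-07 in dnBrg1, 2.39e-06 in dnChd4 and 4.67e-07 in dnSnf2h, and 0.403 in control. With an estimated correlation these became adjusted p = 0.745, 0.68, 0.82 and 0.91. Of 27 S phase and DNA replication genes, 24 fell in control, 17 in dnBrg1, 23 in dnChd4 and 22 in dnSnf2h (24, 22, 25 and 23 adjusted over the list alone, with 1 rise in dnBrg1). Examples are the thymidine kinase gene Tk1 at -1.77, -0.97, -0.77 and -0.87 and Mcm7 at -0.79 in dnBrg1 and -0.83 in dnChd4. Camera with 17 arrays gave adjusted p = 0.00692, 2.39e-06 and 5.15e-07 in the dominant-negative lines and 0.103 in control (adjusted p = 0.896, 0.68, 0.82 and 0.91 with an estimated correlation).

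Of 20 amino acid stress genes of the ATF4 programme, with 15 arrays 17 fell in control, 7 in dnBrg1 (where 1 rose), 15 in dnChd4 and 15 in dnSnf2h (17, 8, 16 and 15 adjusted over the list alone). The serine synthesis gene Psat1 fell by 1.95 in control, 1.02 in dnBrg1 and 1.46 in dnSnf2h, and the folate enzyme gene Mthfd2 by 1.92, 1.30 and 1.45 in control, dnChd4 and dnSnf2h. Camera with 17 arrays called the list lower in dnChd4 (adjusted p = 1.62e-05) and dnSnf2h (adjusted p = 9.53e-06), not in dnBrg1 (0.322) or control (0.58). Both calls were lost with an estimated correlation (adjusted p = 0.68 and 0.82). Glycolysis and hypoxia genes followed, with 9 fallen and 1 risen of 20 in dnChd4 and 8 and 1 in dnSnf2h (9 and 1, and 10 and 1, adjusted over the list alone), such as Hk2 (-0.97 in dnChd4), Vegfa (-0.88 in dnChd4) and Pfkp (-0.83 in dnSnf2h). Camera gave adjusted p = 0.0476 in dnChd4 and 0.00166 in dnSnf2h (adjusted p = 0.68 and 0.82 with an estimated correlation). In dnBrg1, 5 rose, including Bnip3 (0.76) and P4ha1 (0.59), and 5 fell, including Ndrg1 (-1.01), and the list had no call (6 and 7 adjusted over the list alone). In control 9 fell (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.91). Of the 21 p53 targets 11 rose and 3 fell in control with 15 arrays (11 and 3 adjusted over the list alone), and 4 rose and 2 fell in dnSnf2h (5 and 2 adjusted over the list alone; camera adjusted p = 0.061).

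**Figure D3:**
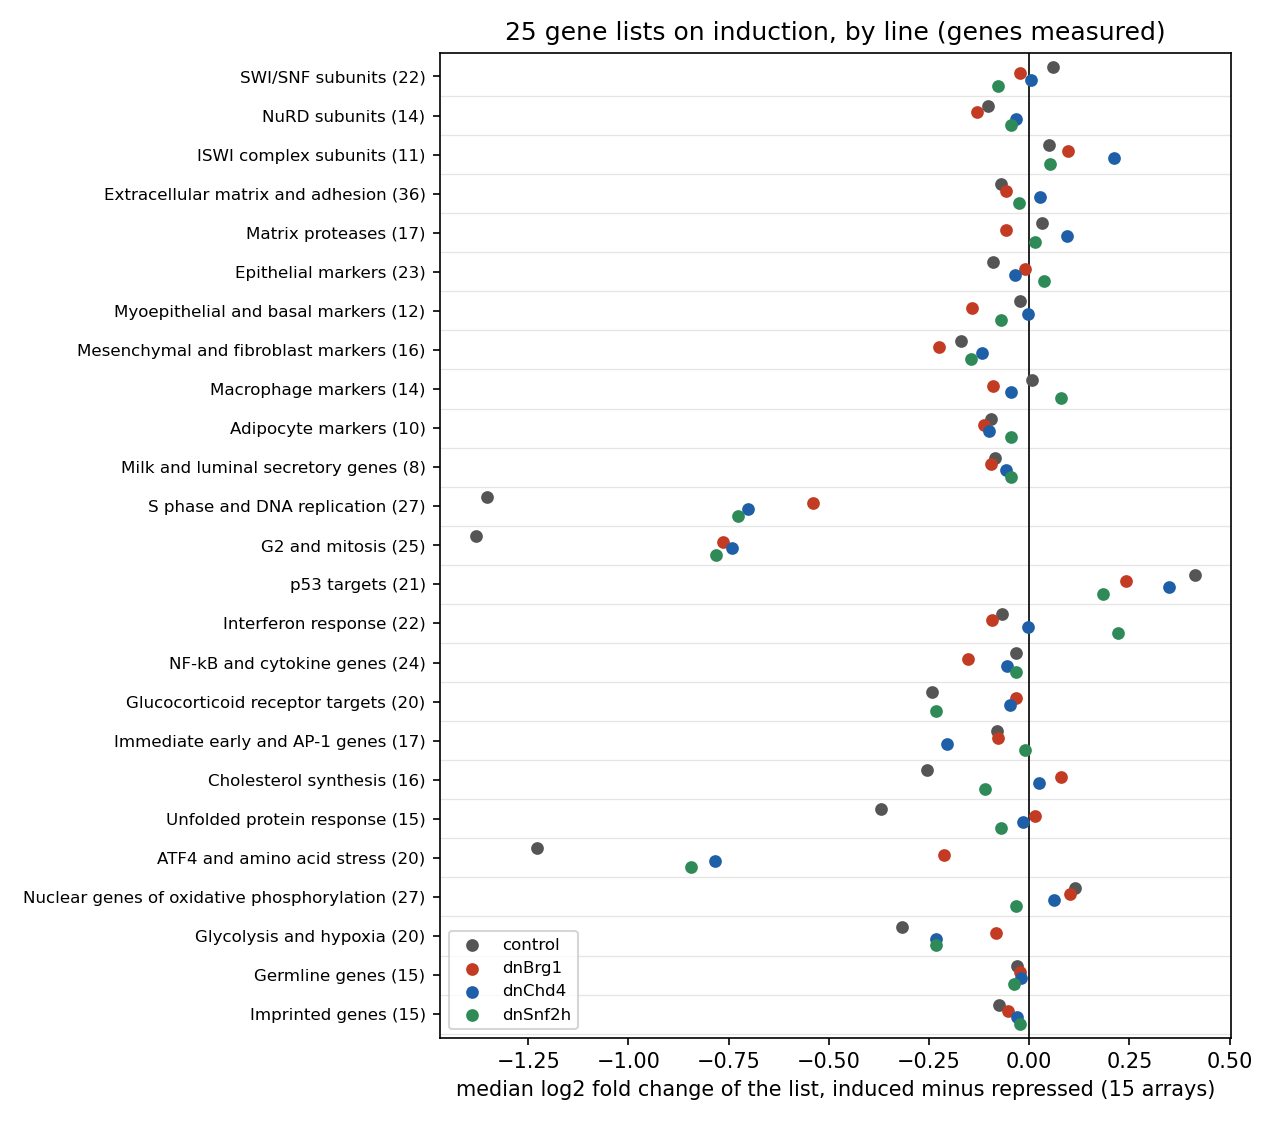
Median log2 fold change on induction (induced minus repressed, 15 arrays) of the measured members of 25 gene lists in the 4 lines; 1 point per line, with no error bar. The S phase, G2 and ATF4 lists stand apart on the lower side, with the G2 list at -1.38 in control and between -0.78 and -0.74 in the other lines, and most other lists lie near 0.

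The other lists had no camera call in any line with 17 arrays, and their counts with 15 arrays were mixed. Of 22 SWI/SNF subunits, 1 rose and 3 fell in dnBrg1, 2 and 3 in dnChd4 and 1 and 2 in dnSnf2h (2 and 3, 2 and 3, and 1 and 2 adjusted over the list alone). Smarcc1 changed by -0.47 in dnBrg1, and Actl6a by between -0.53 and -0.35 in the 3 lines. Of 11 ISWI subunits, 0 rose and 1 fell in dnBrg1, 1 and 2 in dnChd4 and 3 and 1 in dnSnf2h (1 and 1, 5 and 2, and 4 and 1 adjusted over the list alone), with Baz1b at -0.50 in dnBrg1 and Baz2a at 0.57 in dnSnf2h. Baz2a was also higher in dnChd4, by 0.48, and in control, by 0.96. The control direction with 15 arrays rests on which arrays were left out. Extracellular matrix and adhesion genes, 36 in number, gave 5 rises and 6 falls in dnBrg1, 11 and 3 in dnChd4 and 4 and 7 in dnSnf2h (5 and 7, 12 and 3, and 4 and 7 adjusted over the list alone). The lysyl oxidase gene Lox fell in every line, by 1.33 in control, 1.16 in dnBrg1, 0.91 in dnChd4 and 1.19 in dnSnf2h. Col5a2 rose by 1.47 in dnChd4 and 1.16 in dnSnf2h. It was also higher in control, by 1.499, so its rise is not shown to be special to those lines. Among 23 epithelial markers the plakoglobin gene Jup rose by 0.48, 1.34 and 1.16 in the 3 lines, and 1 rose and 1 fell in dnBrg1, 1 rose in dnChd4, and 2 rose and 1 fell in dnSnf2h (the same counts adjusted over the list alone). Of 17 immediate early and AP-1 genes, 2 rose and 3 fell in dnBrg1, 1 and 3 in dnChd4 and 0 and 4 in dnSnf2h (2 and 3, 1 and 4, and 0 and 4 adjusted over the list alone), with Myc at -0.70, -1.16 and -1.29. Of 15 unfolded protein response genes, 2 rose and 2 fell in dnBrg1, 4 and 2 in dnChd4 and 1 and 3 in dnSnf2h (2 and 2, 5 and 3, and 1 and 5 adjusted over the list alone), and Herpud1 fell by 0.51, 0.80 and 0.92. Herpud1 fell further in control, by 1.51. Cholesterol synthesis, with 16 genes, gave 2 rises and 1 fall, 3 and 0, and 0 and 4 (3 and 1, 3 and 0, and 1 and 5 adjusted over the list alone), with Hmgcs1 at -0.54 in dnBrg1. Of the 10 adipocyte markers Cd36 rose in dnBrg1 and none passed in dnChd4 or dnSnf2h (1, 0 and 0 adjusted over the list alone), while Lpl (-0.48) and Cebpa (-0.46) fell in control (4 falls adjusted over the list alone). Of 8 milk and luminal secretory genes only Xdh passed in the dominant-negative lines, and fell by 0.46, 0.53 and 0.55 (1 higher and 1 lower, 0 and 1, and 0 and 1 adjusted over the list alone). None of the 15 germline genes passed in any line (0 adjusted over the list alone, limma), the largest change in a dominant-negative line being Sycp3 at 0.26 in dnChd4 (adjusted p = 0.0703). Of 15 imprinted genes, Igf2r rose in dnChd4, by 0.88 (1 adjusted over the list alone).

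Other counts with 15 arrays follow, without the control line unless named. Mesenchymal markers gave 0 rises and 2 falls in dnChd4 and 0 and 6 in dnSnf2h, and NF-kB genes 4 and 3, and 4 and 5 (5 and 4, and 5 and 7 adjusted over the list alone). Glucocorticoid receptor targets gave 3 rises and 4 falls in dnChd4, with Dusp1 at 0.79 and the metallothionein gene Mt2 at -0.90, and 3 and 6 in dnSnf2h, with Mt1 at -0.87 (4 and 4, and 3 and 6 adjusted over the list alone). Interferon genes gave 3 rises in dnBrg1, led by Irf7 (0.58), and 3 in dnChd4, led by Ddx58 (0.90) and Irf7 (0.85), with 0 falls in either (5 and 3 rises adjusted over the list alone). The control change of Irf7 was larger, at 1.13. Matrix proteases gave 3 rises and 4 falls in dnBrg1, with Adamts1 at -1.24, and 3 and 1 in dnSnf2h (the same counts adjusted over the list alone). NuRD subunits gave 2 and 1 in both dnBrg1 and dnSnf2h (2 and 2, and 3 and 2 adjusted over the list alone). Macrophage markers gave 1 rise and 2 falls in control, 1 and 1 in dnBrg1 and 2 and 1 in dnSnf2h (the same counts adjusted over the list alone). Lyz2 rose in each of them, by 1.47, 1.34 and 1.36, so its rise was not special to dnChd4, and Cd68 fell by 0.48 in dnBrg1. Myoepithelial and basal markers gave 2 and 2 in control, 0 and 1 in dnBrg1 and 2 and 1 in dnSnf2h (the same counts adjusted over the list alone). Krt14 fell in each, by 1.06, 1.29 and 1.29, and Acta2 rose by 1.93 in control and 2.32 in dnSnf2h.

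The inductions were next compared with the control induction. With 17 arrays this takes off little of any response shared with control, because the control arrays oppose each other: the control fold changes had an SD of 0.149 across genes, against 0.45 with 15 arrays. In the dnBrg1 line 18 genes differed, 11 higher and 7 lower. Csnk1g1 (2.91, SE 0.244; adjusted p = 0.000189), Auts2 (2.15; adjusted p = 9.63e-05), Slc40a1 (1.93) and Cd36 (1.40) led on the higher side, and Saa3 (-2.53; adjusted p = 0.00154), Ccl7 (-2.34), Cxcl12 (-1.70; adjusted p = 0.0394) and Loxl1 (-1.28) on the lower side. Loxl1 began at similar levels in both lines, 8.31 ± 0.04 in control and 8.25 ± 0.10 in dnBrg1 (SD, n = 2 each). Saa3 (3.98 and 10.63), Ccl7 (6.62 and 9.62) and Cxcl12 (7.51 and 9.30) began lower in control, which had less room to fall, so part of these differences may come from the starting level. In dnChd4 8 genes differed, with Susd2 at 2.68 (SE 0.225; adjusted p = 0.000275), Madcam1 at 2.18, Pld4 at 1.95 and Chd4 at 1.83 higher, and Zfp36l1 at -0.87 (adjusted p = 0.0481) as the 1 lower gene. That call was fragile: it was kept with quantile normalization and with 15 arrays (adjusted p = 0.0175) and lost under the other fits of these arrays and in most with 1 array left out, with adjusted p = 0.632 when only the groups concerned were fitted and 0.246 with centring. Kiss1r, at -0.48, did not pass. In dnSnf2h limma called 0 genes and 1121 had an unadjusted p under 0.05. The nearest were Zfp36l1 at -0.90 and Saa3 at -1.79 (adjusted p = 0.185 for both), Gbp3 at 0.79 and Cgnl1 at 1.56 (adjusted p = 0.368). Fits of only the groups concerned gave 4, 3 and 0 calls. The 15-array counts were 585 higher and 801 lower in dnBrg1, 101 and 62 in dnChd4, and 136 and 278 in dnSnf2h, and all 17-array calls were kept. Then dnBrg1 differed from control at Dynap (2.62), Tnnt2 (-2.78), Acta2 (-2.42) and Nppb (-2.40). Every 15-array difference from control includes the control line's own change, whose direction rests on which control arrays were left out. Acta2, for instance, changed by -0.50 in dnBrg1 and by 1.93 in control, and Dynap fell in control in that fit. The carbonyl reductase gene Cbr2 was lower than in control in all 3 lines, by -2.66, -1.86 and -2.29. In dnSnf2h Cavin2 was higher by 1.31, and Saa3 then passed at -1.66 (adjusted p = 0.00856), where it had begun at 3.98 in control and 9.08 in dnSnf2h, which leaves control little room to fall. Leaving out 1 array moved the 17-array counts between 6 (without dnBrg1 repressed replicate 2) and 60, between 5 (without the library labelled control repressed replicate 1) and 16, and between 0 and 19, the highest count each time without control repressed replicate 2.

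The G2, S phase and ATF4 lists changed direction with the fit in these differences, and some other lists did not. G2 and mitosis genes were lower than in control with 17 arrays, with a median of -0.58 in dnBrg1 (camera adjusted p = 0.00368; adjusted p = 0.982 with an estimated correlation). With 15 arrays they were higher, with a median of 0.55 (adjusted p = 1.05e-11; adjusted p = 0.37 with an estimated correlation). The S phase list turned from -0.45 to 0.73 in dnChd4 (camera adjusted p = 0.00593 with 17 arrays; adjusted p = 0.737 with an estimated correlation). The ATF4 list turned from -0.73 to 0.35 in dnSnf2h (camera adjusted p = 0.0015; adjusted p = 0.923 with an estimated correlation). Macrophage markers in dnChd4 kept their direction, with medians of 0.11 and 0.14 (camera adjusted p = 0.00109 with 17 arrays; adjusted p = 0.0672 with an estimated correlation), as did interferon genes in dnSnf2h, with 0.22 and 0.14 (camera adjusted p = 0.000226; adjusted p = 0.183 with an estimated correlation).

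The remodelers were then compared with each other by the difference of their inductions, which needs no control array. Higher and lower here refer to the change on induction, not to the level. Between dnBrg1 and dnChd4 26 genes differed, 7 higher and 19 lower in dnBrg1. Csnk1g1 (2.75, SE 0.255; adjusted p = 0.000304), Auts2 (2.29), Slc40a1 (1.61) and Cd36 (1.52) were higher in dnBrg1, and Susd2 (-2.74), Ccl7 (-2.27), Madcam1 (-2.24) and Chd4 (-2.04; adjusted p = 0.000185) were lower. Between dnBrg1 and dnSnf2h 7 genes differed, among them Csnk1g1 (2.76), Auts2 (2.23; adjusted p = 0.000102), Slc40a1 (1.66), Hs3st1 (1.48), Ccl7 (-2.05) and Mmp3 (-1.29; adjusted p = 0.0311). Between dnChd4 and dnSnf2h 8 genes differed, all higher in dnChd4, with Susd2 at 3.03 (adjusted p = 0.000218), Pld4 at 2.28, Chd4 at 1.86 and Ly6f at 1.57. Rtp4 at -1.13 and Gbp3 at -0.80, both interferon-induced, did not pass with 17 arrays and passed with 15 (adjusted p = 0.00428 and 0.0309). The 15-array counts were 288, 153 and 33, and the pairs of lines alone gave 445, 65 and 21. Leaving out 1 array from the 17 moved the counts between 10 (without dnBrg1 induced replicate 2) and 41, between 3 (without dnBrg1 induced replicate 1) and 12, both highs without the library labelled control induced replicate 1, and between 4 (without dnChd4 repressed replicate 1) and 9. Several single genes were lower in dnBrg1 with 15 arrays: Acta2 by -3.05 against dnChd4 and -2.82 against dnSnf2h, Mcam by -3.04 and Ms4a4d by -2.74 against dnChd4, and Nppb by -2.07 and Tnnt2 by -1.96 against dnSnf2h. Cyp2b13 was higher in dnBrg1 than in dnSnf2h by 1.57. Dynap was higher than in dnChd4 by 1.6. Ms4a4d and Tagln were higher in dnChd4 than in dnSnf2h by 1.95 and 1.93, and Clu was lower by -0.71 (adjusted p = 0.047).

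The lists were compared by the same differences of inductions, not by levels. Extracellular matrix genes and matrix proteases were lower in dnBrg1 than in dnChd4, with median differences of -0.22 over 36 genes and -0.31 over 17 (camera adjusted p = 0.00103 for both). Both calls held with an estimated correlation with 17 arrays (adjusted p = 0.0262 for both) and not with 15 (adjusted p = 0.0792). In the matrix list 1 gene was lower with 17 arrays, and 1 was higher and 5 lower with 15 (1 and 11 adjusted over the list alone). Interferon genes were lower in dnBrg1 than in dnSnf2h, with a median of -0.27 (camera adjusted p = 1.08e-05; adjusted p = 0.0871 with an estimated correlation), and lower in dnChd4 than in dnSnf2h, at -0.13 (camera adjusted p = 0.000161; adjusted p = 0.0836 with an estimated correlation). ATF4 genes were less low in dnBrg1 than in dnChd4 (median difference 0.36; camera adjusted p = 0.00263; adjusted p = 0.769 with an estimated correlation) and than in dnSnf2h (0.50; camera adjusted p = 0.00137; adjusted p = 0.738 with an estimated correlation).

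The overlap of calls depended on the fit. With 17 arrays, 1 gene, Zfp36l1, fell in all 3 dominant-negative lines: by 0.78 in dnBrg1 (adjusted p = 0.0028), 0.88 in dnChd4 and 0.90 in dnSnf2h, with 0.00 in control (15 arrays). When each array was centred on its median dnSnf2h had no call, so no gene was shared by all 3. With each line alone, 1004 genes were called the same way in all 3, against 11.6 for independent lists. With 15 arrays the number was 1618, 974 higher and 644 lower, against 26.9. By pair, 1911 were shared by dnBrg1 and dnChd4 (288 expected), 1921 by dnBrg1 and dnSnf2h (274.9 expected) and 2512 by dnChd4 and dnSnf2h (348.3 expected), and 25, 16 and 6 went in opposite directions. Leaving out 1 of the 17 arrays moved the number shared by all 3 between 0 (without dnBrg1 repressed replicate 1, among others) and 22 (without the library labelled control induced replicate 1). With 15 arrays 1527 of the 1618 were called the same way in the control line and 0 the opposite way. That direction depends on which control arrays were left out, and with 17 arrays limma called 0 control genes (845 at an unadjusted p under 0.05). Of the 15-array calls of each line, 71.2% in dnBrg1, 82.4% in dnChd4 and 77% in dnSnf2h were also control calls in the same direction. With those genes left out, 91 remained in all 3 lines, 53 higher and 38 lower, and 187, 208 and 194 by pair. Of these 91, 85 had the same sign in control without a call, so they are not shown to be free of a control response, and the 0.29 expected for independent lists does not allow for it. A gene that passed in the dominant-negative lines and not in control is not thereby shown to differ from control.

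The genes named from these 91 were Tinagl1, a matrix protein gene (1.14 in dnBrg1, 0.62 in dnChd4 and 0.51 in dnSnf2h, with 0.07 in control), Cmbl (1.09, 1.09, 0.62 and 0.56), the muscle kinase gene Dmpk (0.61, 1.20, 0.73 and 0.11), the mechanical-stress gene Ankrd1 (0.56, 0.66, 0.67 and -0.17), Mtmr10 (0.73, 0.56, 0.56 and 0.28), the ezrin gene Ezr (0.76, 0.63, 0.55 and 0.27), Sync (0.66, 1.17, 0.54 and 0.35) and the cytokine gene Ctf1 (0.50, 0.58, 0.56 and 0.37) on the higher side. On the lower side they were Zfp36l1, Clec2d (-0.79, -0.73, -0.83 and -0.02), Vcan (-1.65, -0.83, -0.71 and -0.58), Usp43 (-0.79, -0.68, -0.81 and -0.32), the acute-phase gene Orm3 (-1.28, -0.57, -0.87 and -0.07), the latent TGF-beta binding gene Ltbp4 (-1.06, -0.54, -0.73 and -0.22), Saa3 (-2.03, -0.54, -1.29 and 0.37) and Pcdh19 (-0.59, -0.50, -0.72 and -0.34). Across all 19938 genes the fold changes of dnBrg1 and dnChd4 correlated with r = 0.672, those of dnBrg1 and dnSnf2h with 0.69 and those of dnChd4 and dnSnf2h with 0.772 (Spearman 0.555, 0.551 and 0.586). No arrays are shared between these inductions. The control induction correlated with them at 0.361, 0.478 and 0.4 with 17 arrays and at 0.665, 0.827 and 0.768 with 15. Without control repressed replicate 2 the first 3 values were -0.425, -0.516 and -0.534.

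Before induction the lines already differed. Compared with the repressed control line, the acute-phase genes Lcn2 and Saa3 and the deubiquitinase gene Usp17ld were higher in all 3 lines. Lcn2 was higher by 5.02 (SE 0.208) in dnBrg1, 5.49 in dnChd4 and 5.95 in dnSnf2h, from 5.09 ± 0.22 (SD, n = 2) in control. Saa3 was higher by 6.65, 4.74 and 5.10, but it read 3.98 ± 0.28 (SD, n = 2) in control, below the mean of 4.77 that bounds the dimmest 30% of genes, so these differences are lower bounds if that reading is background. Usp17ld was higher by 4.83, 4.92 and 4.65. S100a7a was lower by -3.72, -2.50 and -3.11. The endothelial cadherin gene Cdh5 (-3.61) and the nidogen gene Nid1 (-3.02) were lower in dnBrg1, the histone gene H2bc4 (-2.40) and the casein gene Csn3 (-1.60) in dnChd4, and n-R5s136 (-2.33) and H2bc4 (-2.16) in dnSnf2h. Cdh5 and Nid1 read below 4.77 in repressed dnBrg1, so these 2 differences are lower bounds in size if such readings are background. With 15 arrays the rule also named Ccl2 (4.61) and Mcpt8 (-2.14) in dnSnf2h, and Mcpt8 (-1.92) in dnChd4. These 3 comparisons share the control arrays, 1 of which is doubted, so part of their likeness may come from those arrays. The counts were 1576 higher and 1646 lower in dnBrg1, 272 and 253 in dnChd4, and 781 and 1084 in dnSnf2h. Scaling moved the split: with quantile normalization it was 1495 and 2763, 329 and 556, and 772 and 1684, and with arrays centred on their medians 1160 and 2300, 199 and 287, and 676 and 1032. With 15 arrays 5732, 1941 and 3892 genes differed, and with only the 2 groups concerned 34, 3 and 3. Leaving out 1 array gave between 1331 (without dnBrg1 repressed replicate 1) and 4581 (without the library labelled control induced replicate 1), between 33 (without dnChd4 repressed replicate 1) and 2590, and between 226 (without dnSnf2h repressed replicate 2) and 3232, the last highs without control repressed replicate 2.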

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

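The counts and genes in this paragraph were flagged by a test of the difference between 2 inductions with 17 arrays, while the 2 patterns weighed after it were not, and their tests and bounds were chosen after the results were seen. Against the control induction, 18 genes differed in dnBrg1 and 8 in dnChd4. Csnk1g1 differed by 2.91, Auts2 by 2.15, Slc40a1 by 1.93, Cd36 by 1.40, Saa3 by -2.53, Ccl7 by -2.34, Cxcl12 by -1.70 and Loxl1 by -1.28 in dnBrg1. Susd2 differed by 2.68, Madcam1 by 2.18, Pld4 by 1.95, Chd4 by 1.83 and Zfp36l1 by -0.87 in dnChd4. Between dnBrg1 and dnChd4 26 genes differed, with Csnk1g1 at 2.75, Auts2 at 2.29, Slc40a1 at 1.61, Cd36 at 1.52, Susd2 at -2.74, Ccl7 at -2.27, Madcam1 at -2.24 and Chd4 at -2.04. Between dnBrg1 and dnSnf2h 7 differed, with Csnk1g1 at 2.76, Auts2 at 2.23, Slc40a1 at 1.66, Hs3st1 at 1.48, Ccl7 at -2.05 and Mmp3 at -1.29. Between dnChd4 and dnSnf2h 8 differed, with Susd2 at 3.03, Pld4 at 2.28, Chd4 at 1.86 and Ly6f at 1.57. All of these calls were kept with 15 arrays, a fit chosen after the data were seen and with a smaller residual SD (0.109 against 0.14). Fits of only the groups concerned gave 4 and 3 calls in dnBrg1 and dnChd4 against control, and Zfp36l1 did not pass there. Between the dominant-negative lines such fits gave 445, 65 and 21 calls. Csnk1g1, Auts2, Slc40a1 and Ccl7 in dnBrg1, and Susd2, Pld4 and Chd4 in dnChd4, stood apart from both of the other dominant-negative lines. Saa3, Ccl7 and Cxcl12 began lower in control than in dnBrg1, so part of their differences from control may come from the starting level. For Chd4 the change may be the expressed transgene itself.

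The first pattern weighed, with tests and bounds chosen after it was seen, is the grouping of control arrays against their labels. The library labelled control repressed replicate 1 differed from control repressed replicate 2 along the mean induction of the other lines (r = 0.798), and control induced replicate 1 differed from replicate 2 in the opposite sense (r = -0.815). An exchange of these 2 libraries, or of their cultures or media, could give both values, as could an exchange that involved the other 3 control arrays, and the values do not separate those causes. A difference in the distribution of signals is ruled out as the whole cause, since r stayed at 0.801 after quantile normalization. A batch effect on genes unrelated to those of the induction would not give r = -0.815. The value cannot exclude a batch effect that moves the same genes as induction. Nothing outside the arrays was available to test the labels.

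The second pattern, again with tests and bounds chosen after it was seen, is that the dominant-negative inductions moved the same genes the same way. A response to tetracycline removal or to the transactivator, which all lines share, stays open. The control induction correlated with their mean at r = 0.841 with 15 arrays, but the 2 control arrays left out gave r = -0.815. The sign by label therefore rests on that choice and does not decide the cause. Whatever the labels, control arrays differed from each other along these genes, as in control repressed replicate 2 minus control induced replicate 2 (r = -0.831). Control repressed replicate 2 minus control induced replicate 1 gave r = -0.0501. The same genes thus moved together in arrays labelled as a line with no dominant negative. Fewer dividing cells after induction also fits, since at least 24 of the 25 G2 and mitosis genes fell in each line. That bound was set knowing the count, so the fit carries little weight, and the genes do not tell cause from consequence. Dim probe sets are ruled out, since the lowest correlation without them was 0.705, and whether loss of remodeler activity adds to the shared genes was not tested. Of the tests tried, 1 on the Smarca4 probe set was run and then dropped, because a probe set need not see the transgene.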

How the results depend on the processing

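Each group had at most 3 arrays. No background values were used here, so what low signal limits was examined only by leaving out the dimmest 30% of genes. Named genes reversed under 1 setting alone. It leaves out both doubted control arrays, was chosen after the data were seen, and turned Glrx (-1.20), Pgap1 (-1.09) and Hsdl2 (-1.09) in dnChd4 minus control, Dynap (1.46), Rrs1 (1.37), H2ac4 (1.24), Cpeb4 (-1.71) and Naip5 (-1.67) in dnSnf2h minus control, and Chd3 (0.43) in control. It also turned medians of lists against control, such as G2 and mitosis from -0.58 to 0.55 in dnBrg1, S phase from -0.45 to 0.73 in dnChd4 and ATF4 from -0.73 to 0.35 in dnSnf2h. With it 5310, 2976, 3747 and 3659 genes were called on induction in control, dnBrg1, dnChd4 and dnSnf2h, 1386, 163 and 414 in the differences from control, 288, 153 and 33 between the dominant-negative lines (dnBrg1 and dnChd4, dnBrg1 and dnSnf2h, dnChd4 and dnSnf2h, an order kept below), and 5732, 1941 and 3892 in the repressed lines. Overlaps became 1911, 1921, 2512 and, in all 3, 1618, and 187, 208, 194 and 91 without genes shared with control. Correlations of control with dnBrg1, dnChd4 and dnSnf2h became 0.665, 0.827 and 0.768, and 5 lists were called in control. The residual SD falls when arrays that disagree with their group are left out, which accounts for part of the added calls by construction.

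Fits of only the groups concerned gave 2938, 4168 and 1446 calls on induction, 4 and 3 in dnBrg1 and dnChd4 against control, 445, 65 and 21 between lines, and 34, 3 and 3 in the repressed lines, where few arrays remain. Their overlaps, added after the data were seen, were 1979, 1061, 1295 and 1004. Array weights gave 2922, 5238 and 670 on induction, 343, 30 and 18 between lines, and 1396, 98 and 79 in the repressed lines. Direct comparison of induced lines gave 2658, 699 and 728, and includes differences between lines before induction. The dnSnf2h induction had 3 calls with trended robust eBayes, 3 without the dimmest 30% of genes, 5 with quantile normalization, 0 with centring and 2 over all probe sets. Without the dimmest genes dnBrg1 minus control gave 11, dnBrg1 minus dnSnf2h 4 and the dnChd4 and dnSnf2h overlap 2, with correlations of 0.705, 0.730 and 0.813 between the lines. Quantile normalization gave 885 in the repressed dnChd4 line. All probe sets gave 7 and 5 in dnBrg1 and dnChd4 minus control, 5 in dnChd4 minus dnSnf2h, and 5762, 1277 and 3863 in the repressed lines, over more tests. List calls went from 6, 6 and 5 to 0, 0 and 0 with an estimated correlation, with 17 arrays and again with 15 (0, 0 and 0), and to 3, 4 and 1 with fry. Of the 17 lists called by camera fry kept 4: NF-kB in dnBrg1, p53 targets and matrix proteases in dnChd4 and interferon in dnSnf2h. For these other moves the cause was not tested.

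With the replicate number as a block, calls went to 12 in dnChd4, 0 in dnSnf2h, 10 in dnBrg1 minus control and 251 in the repressed dnChd4 line, and overlaps to 0 for dnBrg1 and dnSnf2h, 0 for dnChd4 and dnSnf2h and 0 for all 3. Correlations of control with dnBrg1, dnChd4 and dnSnf2h became 0.0282, 0.0844 and 0.0192. These equal the values without control induced replicate 3, the only array with that number, which the block in effect leaves out. The labels do not say that the numbers pair the samples. Deviations of same-numbered arrays correlated at 0.016 in dnBrg1, 0.135 in dnChd4 and 0.313 in dnSnf2h, which shows no strong pairing but cannot exclude shared handling. The value of -0.762 in control does not bear on pairing, because both doubted libraries carry the number 1.

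Leaving out 1 array at a time gave these lowest and highest values. Inductions gave 0 to 4 calls in control, 20 to 426 in dnBrg1, 8 to 262 in dnChd4 and 0 to 128 in dnSnf2h. Differences from control gave 6 to 60, 5 to 16 and 0 to 19, and differences between lines 10 to 41, 3 to 12 and 4 to 9. Repressed lines gave 1331 to 4581, 33 to 2590 and 226 to 3232. Overlaps gave 1 to 62, 0 to 40, 0 to 48 and, in all 3, 0 to 22. Correlations with control turned negative without control repressed replicate 2 and ran from -0.425 to 0.607, -0.516 to 0.774 and -0.534 to 0.714, and between dominant-negative lines from 0.615 to 0.681, 0.606 to 0.690 and 0.644 to 0.797. Counted per gene, comparison and left-out array, calls of named genes were lost 178 times, and none of these genes reversed. Where a left-out array leaves 1 in its group, that array is assumed to vary like the others.

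Counted per gene or list and comparison, 302 named results kept their side of the threshold over all probe sets, 204 with array weights, 163 with 15 arrays, 269 without the dimmest genes, 310 with centring, 310 with trended robust eBayes, 192 with only the groups concerned, 306 with quantile normalization and 319 with the block. With 15 arrays 157 passed that had not, and 1 was lost, the matrix protease list in dnChd4.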

Other observations

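A list of lysosome genes was added after some were seen among the largest changes. Of 35 measured, with 15 arrays 20 rose and 1 fell in control, 21 and 1 in dnBrg1, 21 and 0 in dnChd4 and 17 and 1 in dnSnf2h (21 and 1, 24 and 1, 24 and 0, and 18 and 1 adjusted over the list alone). The proton pump subunit gene Atp6v1a rose by 2.35 in control (SE 0.134; adjusted p = 1.24e-08), 1.80 in dnChd4 and 1.55 in dnSnf2h. The sialidase gene Neu1 rose by 1.53 in dnBrg1 and 1.45 in dnSnf2h, the cathepsin gene Ctso by 2.51 in control and 1.45 in dnChd4, Pld3 by 2.01 in control and 1.48 in dnSnf2h, and the folliculin gene Flcn by 0.91 in dnBrg1 and 1.32 in dnChd4. The median change was 0.52, 0.42, 0.37 and 0.23 in control, dnBrg1, dnChd4 and dnSnf2h. No member passed with 17 arrays, and no camera result is given for this list, because it came from the same values.

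The arrays of the repressed dnSnf2h line were closest to an array of another line: replicates 1 and 2 both correlated best with dnChd4 repressed replicate 1 (r = 0.997 and 0.994), and dnSnf2h induced replicate 2 with dnChd4 induced replicate 2 (r = 0.997). In dnBrg1 and dnChd4 every array was closest to its own replicate.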
